A study of Mus musculus with 58 samples.

How the data were processed

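RNA was measured by sequencing in liver and kidney of male B6C3F1 mice, a first-generation hybrid strain, after 1 intragastric dose of trichloroethylene (TCE), tetrachloroethylene (PCE) or vehicle. The chemicals are chlorinated solvents that differ by 1 position, where PCE has chlorine and TCE has hydrogen. The vehicle was 5% Alkamuls EL-620, a castor oil surfactant, in saline, given at 5 mL/kg. Libraries were made from total RNA with a TruSeq kit and read on an Illumina HiSeq instrument, per the labels' protocols. The protocol text names B6C3F1 mice while another label names C57BL/6, and the time between dose and sampling was not given in the sources used here.

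The deposited tables, 1 per tissue, hold raw read counts per RefSeq transcript, not normalized, with 1 column for each library and no pooling of replicates, per the file headers. The deposited columns of the 0.22 and 0.67 mmol/kg libraries have a decimal dose above the values and were therefore read under the unit of expected counts. Every value below that line was a whole number, so rounding changed none. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.10, HTSeq and the genome build mm10, without their roles. The annotation version, the strand setting and the filters were not given in the sources used here. HTSeq sets reads that match several overlapping features aside in an ambiguous line, which held 19.68 to 22.55% of each library. Reads matching no feature made up 14.29 to 22.29% in liver and 20.49 to 27.53% in kidney. Both lines were left out of library totals and tests. Counts of genes with several isoforms, overlapping neighbours, antisense partners or near-identical relatives, such as the Cyp4a and Acot families, are therefore uncertain in level.

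Each table has 33392 transcripts. Of these, 32988 were matched by accession to the RefSeq gene table of GRCm38.p6, 278 were named from the deposited symbol and 126 had no name and stayed under their accession. Counts were summed to 24122 genes, 5039 of them with 2 or more transcripts. Chromosome positions are 1-based and come from that table, whose primary chromosomes are those of mm10. Levels are given as CPM, computed here as counts divided by TMM-normalized library sizes and scaled to a fixed total.

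Library totals were 30932385 to 125880542 counts in liver and 23247565 to 32420329 in kidney. Liver depth differed with dose by design, per the series' design text, since the vehicle and 6 mmol/kg libraries held 88048143 to 125880542 and the others 30932385 to 65112568. The 10 most abundant genes took 22.93 to 28.3% of a liver library and 12.95 to 19.12% of a kidney library. Every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of at least 13.57 over 56 pairs. Labels do not say what a replicate number marks, and p-values measure the spread between these samples.

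Each dose was compared with the vehicle group of its own chemical in edgeR 4.0.16 (R 4.3.3). The steps were TMM normalization, the filterByExpr count filter, estimated dispersions, a robust quasi-likelihood fit with 1 mean per group and the quasi-likelihood F test. The 10 groups of a tissue shared 1 fit, of 13174 genes in liver and 14216 in kidney. The common biological coefficient of variation was 0.257 in liver and 0.156 in kidney. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and every test was two-sided. A standard error (SE) is the absolute log2 fold change divided by the square root of F. Dose trends were fitted within 1 chemical and tissue on the dose rank, 0 to 4, and are given as log2 change per rank. The response to PCE was compared with that to TCE at each molar dose as a difference of both fold changes, with 95% intervals. The liver and kidney responses at 6 mmol/kg were compared in 1 fit of all 58 libraries and 14949 genes.

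The comparisons, 19 lists of genes by function, 16 lists of cell type markers and the rule for naming genes were fixed before the data were examined. The rule takes, at 6 mmol/kg, the 5 higher and 5 lower called genes with the largest fold change and a mean of at least 1 CPM, without predicted names, and the called member of each function list with the smallest adjusted p. At lower doses and for differences between responses it takes 3 and 3. Cyp4a14, Acot1, Cyp2b10, Cyp2e1, Cyp7a1, Cdkn1a and Havcr1 are reported whatever their result, as ranges where they were not called, Cyp7a1 in liver and Havcr1 in kidney, and both between tissues. Other genes were chosen after their values were seen, and the text says so. A gene that the rule names is not reported here. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with a correlation estimated for each list, and with fry. Adjustment was over the lists of 1 kind in 1 comparison. The symbol Cyr61 was matched to Ccn1, while Igkc, Ighm and Ly6g were not matched and not used here.

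Alternatives were DESeq2's size factors in edgeR, no count filter, DESeq2 1.42.0, each library left out in turn, a block by replicate number, thinning to 30932385 counts in liver and 23247565 in kidney, pooled vehicle groups, a fit of 1 chemical alone, linear dose, and PCE set directly against TCE. Added after seeing the data were slopes of log2 CPM on transcript length and GC content as covariates, fits without 12 liver, 2 kidney or 4 kidney libraries, and tests of single transcripts.

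The tests were run on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For the comparison of 6 mmol/kg PCE with vehicle, edgeR called 43 and 86 of these in liver, with 1 false call in 12986 genes. In kidney it called 55 and 92, with 8 false calls in 14069 genes. DESeq2 called 55 and 89 in liver with 18 false calls, and 59 and 92 in kidney with 26. The simulated libraries held no length or GC slopes or other sample structure, so these false calls do not describe errors in the real libraries.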

Results

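RNA levels were compared across doses of TCE and PCE in mouse liver and kidney, the tissues named in the series title. The design has 58 libraries in 20 groups, formed by 2 tissues, 2 chemicals and 5 dose levels including vehicle. TCE was given at 24, 80, 240 and 800 mg/kg and PCE at 30, 100, 300 and 1000 mg/kg, which the labels pair as about 0.22, 0.67, 2 and 6 mmol/kg. Each group holds 3 libraries, except liver at 0.67 mmol/kg PCE and the kidney vehicle group of PCE with 2 each. Library totals ran from 30932385 to 125880542 counts in liver and from 23247565 to 32420329 in kidney. Fold changes below are log2 values with their SE, levels are mean CPM ± SD, and adjusted p-values come from edgeR.

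The first comparison asked which genes 6 mmol/kg TCE changed in liver. The fatty acid hydroxylase Cyp4a14 (chromosome 4, 115486200 to 115496158) rose from 4.73 ± 6.09 CPM (n = 3) to 1080 ± 361 CPM (n = 3), a change of 7.84 ± 1.34 with adjusted p = 0.00381. The related Cyp4a10 rose by 5.66 ± 0.90 (adjusted p = 0.00223) and Cyp4a31 by 3.48 ± 0.51 (adjusted p = 0.00122). Acot1, an acyl-CoA thioesterase on chromosome 12 (84009502 to 84017670), rose from 9.19 ± 7.32 to 62.8 ± 5.43 CPM, and Acaa1b, a peroxisomal thiolase, rose by 2.15 ± 0.29. Of 44 tested members of the list of PPARa targets and fatty acid oxidation, genes driven by the fatty acid receptor PPARa, 17 rose, none fell and 27 did not pass. Adjusted over the list alone, 31 rose. The list's median change was 0.80, with camera adjusted p = 2.38e-48 and adjusted p = 0.00729 with an estimated correlation.

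Acute phase genes, which the liver makes in inflammation, were lower at that dose. Serum amyloid A gene Saa1 was at 95.1 ± 56 CPM against 10300 ± 9770 CPM in the vehicle group, a change of −6.76 ± 1.56 (adjusted p = 0.0304). Saa2 fell by 9.08, Lcn2 fell by 7.72, Saa3 fell by 6.04 and Orm2 fell by 5.58 on the log2 scale. Of 23 tested members 9 fell, 16 adjusted over the list alone, and none rose, with a median of −1.23 and camera adjusted p = 5.95e-14, but adjusted p = 0.174 with an estimated correlation. The vehicle libraries were uneven, with Saa1 at 19600, 104 and 11300 CPM, and the vehicle group of PCE was at 103, 606 and 170 CPM. Against that group, edgeR called 0 of the 23 members lower and the list's median was 0.02.

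Among 15 tested clock genes, 2 rose, 3 fell and 10 did not pass, while 5 rose and 4 fell adjusted over the list alone. The transcription factor Dbp rose by 3.54 ± 0.53 (adjusted p = 0.00151), Nr1d2 rose by 2.07 and Npas2 fell by 2.11. Nr1d2 and Pdia6 are named here after their values were seen. The list's median was −0.41 and its mean 0.24, and camera found no common direction (adjusted p = 0.861). Rgs16, a regulator of G protein signalling, rose by 4.40 ± 0.79. Ephx1, a microsomal epoxide hydrolase, rose by 1.08 ± 0.18 as the called gene of 24 in the NRF2 and glutathione list. Sox9, Elovl3, Calr and Pdia6 fell by 1.16, 1.12, 0.94 and 0.93. The xenobiotic cytochrome Cyp2b10 (−0.04 ± 0.52), the solvent oxidizing Cyp2e1 (0.18 ± 0.19), the bile acid enzyme Cyp7a1 (0.01 ± 0.55) and the p53 target Cdkn1a (0.64 ± 0.68) did not pass.

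In total 172 genes were called at 6 mmol/kg TCE in liver, 71 higher and the others lower, of 13174 tested, and DESeq2 called 350. With pooled vehicle groups 103 were called, 59 higher and 44 lower, and 73 were shared with the 172. Leaving out vehicle library 3 gave 28, and leaving out dose libraries 1, 2 or 3 gave 58, 45 and 49. With length and GC slopes as covariates 54 were called, and without 12 libraries of low length slope 1151, both added after seeing the data. The latter fit drops vehicle library 1, at −0.183 per doubling. Vehicle libraries 2 and 3, which stay, had slopes of 0.18 and 0.177, against 0.017, −0.031 and −0.01 in the dose libraries. That fit therefore does not remove the difference in length slope between the groups.

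The Cyp4a genes also rose in liver at 6 mmol/kg PCE. Cyp4a14 rose from 5.87 ± 4.19 (n = 3) to 3610 ± 3390 CPM (n = 3), a change of 9.26 ± 1.42 (adjusted p = 0.000952), Cyp4a10 rose by 6.36 ± 0.93 and Cyp4a31 by 4.57 ± 0.53. Acot3 rose by 4.19 ± 0.98, Acot1 by 2.63 ± 0.55, and the peroxisomal enzyme Ehhadh, named after its values were seen, by 3.36 ± 0.40. Rad51b, a gene of homologous recombination (chromosome 12, 79297282 to 79848260), rose from 0.325 ± 0.127 to 5.18 ± 2.02 CPM, by 3.99 ± 0.45 (adjusted p = 5.8e-05). Of the 44 PPARa list members 27 rose, 37 adjusted over the list alone, none fell and 17 did not pass. The list's median was 1.09, camera adjusted p = 1.24e-31, and adjusted p = 0.0586 with an estimated correlation.

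Of 23 members of the list of ER stress and amino acid response, Trib3 (1.30 ± 0.30, adjusted p = 0.0168) and Chac1 (1.98 ± 0.49) rose and Calr (−0.75, adjusted p = 0.0448) fell in liver at 6 mmol/kg PCE, with the same counts adjusted over the list alone. The list's median was −0.34, with camera adjusted p = 0.15 and adjusted p = 0.797 with an estimated correlation. Sesn2, a p53 target, rose by 1.02 ± 0.25. Chac1, Calr, Adgre1, Dcn and Ass1 are named here after their values were seen. The oxidative stress genes Srxn1 and Nqo1 rose by 0.80 ± 0.14 and 1.20 ± 0.28, and 4 of 24 members of the NRF2 list rose with 6 higher and 2 lower adjusted over the list alone. That list's camera test gave adjusted p = 0.201. Nr1d2 rose by 1.85 ± 0.38, Vcam1 by 1.71 ± 0.41, Klf6 by 1.09 ± 0.26 and Cyp3a13 by 0.84 ± 0.22. The macrophage marker Adgre1 (1.42) and the fibroblast marker Dcn (1.30) rose, the former as 1 of 12 macrophage markers with camera adjusted p = 0.0697. Dcn was the sole called member of its list, and the hepatocyte marker Ass1 fell (−1.13, adjusted p = 0.0464). Nat8 fell by 1.06, Elovl3 by 1.16, Mvk by 0.89, Mcm2 by 0.86, Oasl1 by 0.81 and Atp5d by 0.75 on the log2 scale. The largest falls were Clic3 (−3.34 ± 0.48), Cyp2c53-ps (−3.13 ± 0.56), Scand1 (−3.10 ± 0.74), Slc34a2 (−2.92 ± 0.38) and Ptgds (−2.81 ± 0.67). Scand1 was at 1.15 ± 0.531 CPM against 9.86 ± 13.9 CPM, and its change was −0.70 without vehicle library 1, which held 25.9 CPM where the TCE liver libraries held 13.5 to 45 CPM. Cyp2b10 (0.40 ± 0.52), Cyp2e1 (0.57 ± 0.19, adjusted p = 0.0732), Cyp7a1 (−0.41 ± 0.55) and Cdkn1a (1.56 ± 0.67) did not pass.

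This comparison called 770 genes, 301 higher and 469 lower, and DESeq2 called 1532. The genes called lower had a median GC content of 56.2% and those called higher 45.1%, against 49.8% of all tested genes. The slope of log2 CPM on GC content was −0.172, −0.152 and −0.295 per 10 points in the dose libraries against 0.022, 0.238 and 0.012 in the vehicle libraries. With slopes as covariates, added after seeing the data, 318 genes were called, and 50 of the lower and 42 of the higher genes were shared. The 469 lower genes had a median of −0.77 without and −0.43 with the covariates. Without 12 libraries of low length slope, which leaves 1 vehicle library, 3 were called. Leaving out TCE vehicle library 1 gave 1258, TCE 0.67 mmol/kg library 2 gave 1172, PCE vehicle libraries 1 and 2 gave 326 and 246, and dose libraries 1 and 3 gave 56 and 239.

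**Figure D1:**
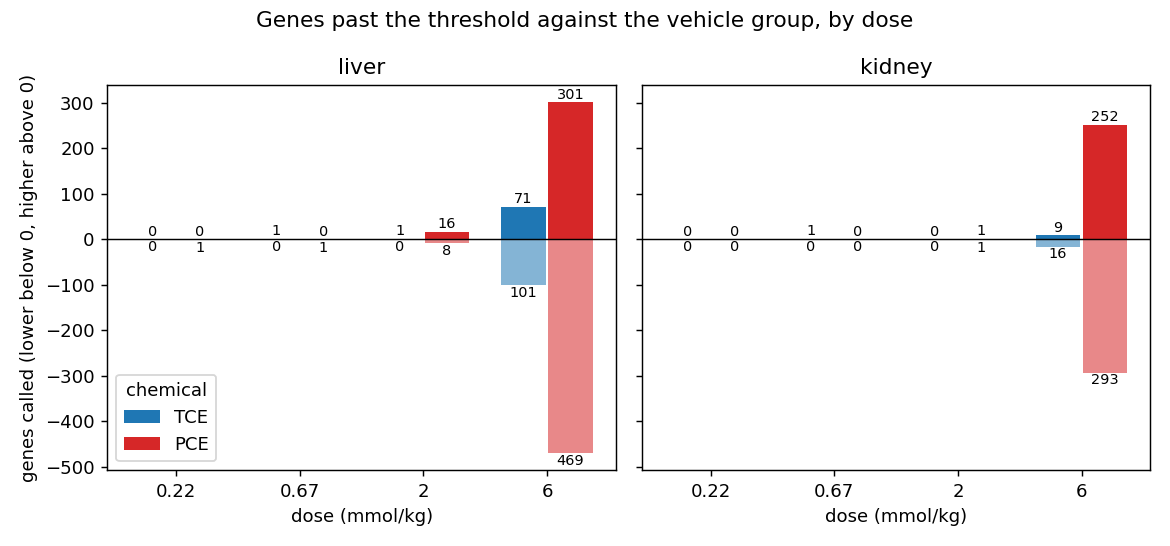
Genes called at an adjusted p under 0.05 against the vehicle group of the same chemical, by dose (x axis, mmol/kg), with higher genes above 0 and lower genes below 0 in lighter colour (y axis, number of genes). At 6 mmol/kg the bars reach 301 higher and 469 lower for PCE in liver and 252 and 293 in kidney, while TCE reaches 71 higher of 172 called in liver, the others lower, and 9 higher and 16 lower in kidney.

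At 2 mmol/kg PCE the liver showed 24 called genes, 16 higher and 8 lower, with Cyp4a14 (6.09 ± 1.24, adjusted p = 0.0375), Cyp4a10 (4.39 ± 0.85) and Rad51b (2.99 ± 0.44, adjusted p = 0.00681) higher. Of the PPARa list 6 of 44 rose, 16 adjusted over the list alone, with adjusted p = 0.166 with an estimated correlation. Fdx2 (−4.47 ± 0.78), Scand1 (−4.10 ± 0.83) and Cyp2c53-ps (−2.68 ± 0.56) were lower, and lost their calls in 7, 13 and 22 of 36 alternatives. The change of Scand1 was −1.70 (adjusted p = 0.349) without PCE vehicle library 1. DESeq2 called 187 genes. The count was 51 without TCE 0.67 mmol/kg library 2, 14 without TCE 6 mmol/kg library 3, 2, 55 and 5 without PCE vehicle libraries 1, 2 and 3, 12 without PCE 0.22 mmol/kg library 2, and 1 and 0 without dose libraries 2 and 3. With the chemical's libraries alone it was 0, and with covariates 1.

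The lower doses in liver called few genes. The call at 0.67 mmol/kg TCE was Rgs16 (4.87 ± 0.81, adjusted p = 0.0487), that at 2 mmol/kg TCE 1110059G10Rik, a predicted gene named after its values were seen (1.06 ± 0.15, adjusted p = 0.00466). The call at 0.22 mmol/kg PCE was Fdx2 (−5.09 ± 0.83, adjusted p = 0.0383), a mitochondrial ferredoxin at 3.31, 0.176 and 1.31 CPM in the vehicle libraries, and at 0.67 mmol/kg PCE Rnf43, an inhibitor of Wnt signalling (−1.42 ± 0.21, adjusted p = 0.00944). At 0.22 mmol/kg TCE edgeR called 0, with 773 genes at an unadjusted p under 0.05 and 29 by DESeq2. At the other 4 doses named here DESeq2 called 42, 57, 29 and 51. At 2 mmol/kg TCE 18 PPARa members rose adjusted over the list alone, none over all genes, and adjusted p = 0.54 with an estimated correlation. At 0.22 mmol/kg TCE the count was 75 without vehicle library 2 and 1 without dose library 2. At 0.67 mmol/kg TCE it was 62 without vehicle library 2 and 0 without any 1 of 20 of the 29 liver libraries. At 2 mmol/kg TCE it was 39 without vehicle library 2, 0 without vehicle library 3 or dose library 3, 4, 2 and 14 without 0.67 mmol/kg libraries 1, 2 and 3, 2 without PCE vehicle library 2 and 4 without PCE 6 mmol/kg library 2. At 0.22 mmol/kg PCE 25 libraries gave 0, while PCE vehicle library 2 gave 38, vehicle library 3 gave 3 and 6 mmol/kg library 2 gave 5. At 0.67 mmol/kg PCE it was 0 without vehicle library 3 or dose library 1, 6 without vehicle library 2, 8 without dose library 2, and 2 without TCE vehicle library 2, 0.22 mmol/kg library 3, 2 mmol/kg library 1 or 6 mmol/kg library 2.

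Of the genes reported whatever their result, Cyp4a14 at 2 mmol/kg PCE was the 1 called in liver at 0.22 to 2 mmol/kg. Otherwise Cyp4a14 was at 1.01 to 4.07 with TCE and at 2.32 and 1.43 with PCE, and Acot1 at 0.58 to 1.69 with TCE and −0.27 to 1.52 with PCE. Cyp2b10 lay between −0.88 and 0.98, Cyp2e1 between −0.09 and 0.23, Cyp7a1 between −1.16 and 0.47 and Cdkn1a between −0.71 and 0.98 (adjusted p of at least 0.249).

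Across doses in liver, Cyp4a14 rose by 1.93 per dose rank with TCE (adjusted p = 0.00352) and by 2.25 with PCE (adjusted p = 0.000293), and Acot1 by 0.67 and 0.69. Cyp2b10 (−0.16 and 0.10), Cyp2e1 (0.03 and 0.14), Cyp7a1 (−0.13 and −0.12) and Cdkn1a (0.17 and 0.37) did not pass. The trend test called 105 genes for TCE, 58 higher and 47 lower, and 1566 for PCE, 626 higher and 940 lower, and DESeq2 called 438 and 2383. The PPARa list rose with both, with 15 of 42 members for TCE and 33 of 43 for PCE, 30 and 37 adjusted over the list alone. Its adjusted p with an estimated correlation was 0.0423 for TCE and 0.0924 for PCE. The genes called lower in the PCE trend had a median GC content of 55.6% and those called higher 44.1%, against 49.7% of all tested genes. With covariates 0 genes were called for TCE and 266 for PCE, 44 of these shared with the 1566. For TCE the count was 258, 51 and 18 without vehicle libraries 1, 2 and 3, 66 and 56 without 0.22 mmol/kg libraries 2 and 3, 171 without 0.67 mmol/kg library 1, and 34 and 23 without 6 mmol/kg libraries 2 and 3. For PCE it was 527 and 2510 without vehicle libraries 2 and 3, and 508 and 457 without 6 mmol/kg libraries 1 and 3.

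The liver responses to both chemicals were compared at equal molar dose. At 6 mmol/kg no gene's change differed past the threshold in edgeR, with 1169 genes at an unadjusted p under 0.05 and 43 called by DESeq2. Cyp4a14 differed by 1.43 with a 95% interval of −1.51 to 4.37 (PCE minus TCE), Acot1 by −0.14 (−1.67 to 1.38), and Ehhadh and Vnn1, chosen after their values were seen, by 0.69 (−0.38 to 1.75) and 1.10 (−0.13 to 2.32). Cyp2b10 (0.44), Cyp2e1 (0.39), Cyp7a1 (−0.43) and Cdkn1a (0.92) did not pass either. The intervals include differences of several-fold. Set directly against TCE without the vehicles, PCE gave 67 genes at 6 mmol/kg, 10 higher and 57 lower. This direct contrast also takes in any difference between the TCE and PCE libraries that was present in vehicle. Its genes therefore cannot be read as differences between the chemicals alone. With covariates the difference of responses gave 3. Across the 13174 genes the fold changes at 6 mmol/kg had Pearson's r = 0.274 and Spearman's rho = 0.28, where genes are not independent replicates, and each chemical had its own vehicle libraries. Both chemicals raised 39 genes, against 1.62 for independent lists, and lowered 27, against 3.6, with 0 in opposite directions. Without TCE vehicle library 2 the difference called 35 genes, and without PCE 2 mmol/kg library 2 or PCE 6 mmol/kg library 2 it called 2 and 4.

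At 0.67 mmol/kg the responses in liver differed for 3 genes. Orm2, an acute phase protein gene, was higher by 8.80 with PCE, and Slc13a5, a citrate transporter, by 5.70 ± 0.94, while Herpud1, an endoplasmic reticulum stress gene, was lower by 2.40 ± 0.41, as −2.40 (each adjusted p = 0.0254). The acute phase list had 1 of 23 members called, 17 higher adjusted over the list alone, a median of 2.61 and adjusted p = 0.0243 with an estimated correlation. This difference takes in the vehicle groups, where Orm2 was at 742 ± 729 CPM for TCE and 30.1 ± 15 CPM for PCE, against 30.3 ± 26.3 and 544 ± 185 CPM (n = 2) at 0.67 mmol/kg. Set directly against TCE without the vehicles, PCE gave 4.17 ± 1.07 for Orm2 (adjusted p = 0.19), 1.76 ± 0.69 for Slc13a5, −1.46 ± 0.31 for Herpud1 and an acute phase median of 1.00, with 0 genes called by edgeR and 819 at an unadjusted p under 0.05. DESeq2 called 53 genes for the difference of responses. The count was 65 without TCE vehicle library 2, 5 without TCE 2 mmol/kg library 1 or 3 or PCE 6 mmol/kg library 1, and 0 without TCE vehicle library 1 or 3, any of the 3 TCE 0.67 mmol/kg libraries, any of the 3 PCE vehicle libraries or PCE 0.67 mmol/kg library 1. At 0.22 and 2 mmol/kg edgeR called 0, with 631 and 914 genes at an unadjusted p under 0.05 and 4 and 3 called by DESeq2. At 0.22 mmol/kg the count was 15, 1 and 3 without TCE vehicle library 2, TCE 0.22 mmol/kg library 2 and PCE vehicle library 2, and at 2 mmol/kg 3 without PCE vehicle library 2. The direct contrast, which also takes in differences present in vehicle, gave 77 and 65 genes at these doses. Cyp4a14, Acot1, Cyp2b10, Cyp2e1, Cyp7a1 and Cdkn1a differed by −1.52 to 2.02 at 0.22 to 2 mmol/kg, with adjusted p of at least 0.791. The vehicle groups of the chemicals, which had the same treatment, differed for 0 genes in edgeR, with 1321 at an unadjusted p under 0.05 and 137 called by DESeq2, and Cyp4a14, Acot1, Cyp2b10, Cyp2e1, Cyp7a1 and Cdkn1a lay between −0.17 and 1.06. This count was 97 without TCE vehicle library 2, 13 without PCE vehicle library 1, 1, 6 and 4 without TCE 0.67 mmol/kg libraries 1, 2 and 3, and 1 without TCE 2 mmol/kg library 1.

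**Figure D2:**
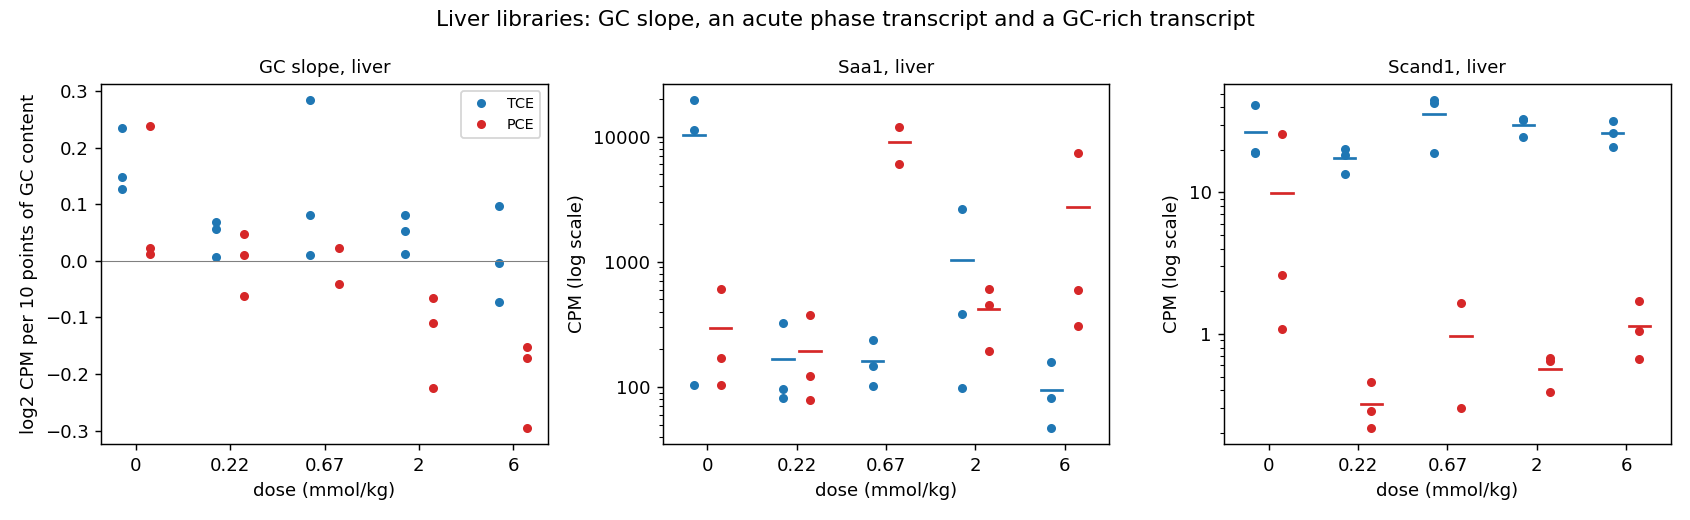
The slope of log2 CPM on GC content per 10 points (left), Saa1 in CPM on a log scale (middle) and Scand1 in CPM on a log scale (right) in each liver library (points), by dose (x axis, mmol/kg) and chemical, with bars at group means of Saa1 and Scand1. The PCE libraries at 6 mmol/kg lie at GC slopes of −0.172, −0.152 and −0.295, and Saa1 is at 19600, 104 and 11300 CPM in the TCE vehicle libraries.

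In kidney, 6 mmol/kg TCE raised Asns and Phgdh among the genes called. Asns, the asparagine synthetase (chromosome 6, 7675165 to 7693209), rose from 6.18 ± 1.15 (n = 3) to 22.9 ± 10.3 CPM (n = 3), by 1.89 ± 0.33 with adjusted p = 0.0211. Phgdh, the first enzyme of serine synthesis, rose by 1.77 ± 0.33, Mthfd2, a mitochondrial folate enzyme, by 1.34 ± 0.28, Pole, a DNA polymerase subunit, by 1.62 ± 0.30, and Fabp1, a fatty acid binding protein, by 1.87 ± 0.32. The transporters Slc22a7 (−1.16 ± 0.23) and Slc7a13 (−0.96 ± 0.18), the nucleotidase gene Nt5e (−1.12 ± 0.22), Rtl6 (−1.19 ± 0.23) and Ifitm7 (−2.26 ± 0.46) were lower. Of 24 members of the list of ER stress and amino acid response 2 rose, among them Asns, and none fell, while 2 rose and 7 fell adjusted over the list alone, with a median of −0.37, a mean of −0.12 and adjusted p = 0.639 with an estimated correlation. Slc7a13 is a marker of the proximal tubule, and it was the 1 of 13 such markers that fell, 1 rose and 3 fell adjusted over the list alone, with camera adjusted p = 0.151. Of the PPARa list 1 of 45 members rose and 10 adjusted over the list alone, with adjusted p = 0.257 with an estimated correlation. Of 28 cell cycle genes Mcm6 rose (0.51 ± 0.10), 9 adjusted over the list alone, with adjusted p = 0.334 with an estimated correlation. Cyp4a14 (3.19 ± 0.74, adjusted p = 0.0821), Acot1 (0.81 ± 0.24), Cyp2b10 (−1.64 ± 0.59), Cyp2e1 (0.00 ± 0.16), Cdkn1a (−0.51 ± 0.36) and Havcr1, a marker of tubular injury (0.23 ± 0.42), did not pass.

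The count in kidney at 6 mmol/kg TCE was 25, 9 higher and 16 lower, and 166 by DESeq2. It was 0 without vehicle library 1 or dose library 1 or 2, 10 without vehicle library 2, 55 without vehicle library 3, 46 without dose library 3 and 53 without PCE 6 mmol/kg library 1. Added after seeing the data, it was 60 with covariates, 49 without 0.67 mmol/kg library 3 and 2 mmol/kg library 2, and 0 without these, dose library 2 and PCE 6 mmol/kg library 3, the 4 libraries with the most adrenal or brown fat RNA. Brown fat's Ucp1 was at 107 CPM in dose library 2 and at most 5.09 CPM in the vehicle libraries. At the lower TCE doses, 0.67 mmol/kg called Slc29a4 (4.08 ± 0.63, adjusted p = 0.0196), named after its values were seen, and 0.22 and 2 mmol/kg called 0. Those had 728 and 606 genes at an unadjusted p under 0.05 and 0 by DESeq2 at both, and 0.67 mmol/kg had 33 by DESeq2. Library 3 of the 0.67 mmol/kg group held Cyp11b1, an adrenal gene, at 566 CPM against at most 1.55 CPM in the other kidney libraries. The count at 0.67 mmol/kg was 200 and 54 without dose libraries 1 and 2, and 0 without dose library 3 or any of the 3 vehicle libraries, and that at 2 mmol/kg was 1 without dose library 1.

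The genes changed in kidney at 6 mmol/kg PCE included PPARa targets. Cyp4a14 rose from 10.5 ± 1.96 (n = 2) to 1050 ± 1240 CPM (n = 3), by 6.63 ± 1.03 (adjusted p = 0.00124). Acot2 rose by 2.04 ± 0.19 (adjusted p = 2.06e-06) and Acot1 by 2.38 ± 0.29 (adjusted p = 8.91e-05). The hormone gene Fgf21 rose by 4.35 ± 0.79 and Pdk4, a kinase acting on pyruvate dehydrogenase, by 3.47 ± 0.79, both named after their values were seen. Of 45 tested PPARa members 30 rose, 36 adjusted over the list alone, none fell and 15 did not pass. The median was 0.69, camera adjusted p = 7.45e-54, and adjusted p = 0.000472 with an estimated correlation.

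Genes of the stress and amino acid response moved both ways in kidney at that dose. Trib3, a stress pseudokinase (chromosome 2, 152337425 to 152344060), rose from 0.696 ± 0.00677 (n = 2) to 9.14 ± 3.09 CPM (n = 3), by 3.71 ± 0.41 (adjusted p = 1.81e-05), Asns by 3.70 ± 0.42, Chac1, which degrades glutathione, by 3.23 ± 0.53 and Phgdh by 1.75 ± 0.37. The chaperone genes Calr, Pdia6, Dnajb11 and Hsp90b1 fell by 0.98, 0.79, 0.71 and 0.73 on the log2 scale. These 4, Chac1, Phgdh and Igfbp1 are named here after their values were seen. Of 24 list members 4 rose and 6 fell, 6 and 8 adjusted over the list alone, with a median of −0.31, a mean of 0.26 and camera adjusted p = 0.259 in the lower direction. Creb3l3 (2.97 ± 0.56) and Igfbp1 (3.38 ± 0.67) rose among 14 genes of gluconeogenesis and fasting, a list with camera adjusted p = 0.00143 and adjusted p = 0.112 with an estimated correlation. Depp1 (3.66 ± 1.03, adjusted p = 0.0484), a target of the fasting factor FOXO, rose, and lost its call in 25 of 38 alternatives.

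Of genes lower in kidney at 6 mmol/kg PCE, Rnf180 (−2.95 ± 0.59), D14Ertd670e (−2.22 ± 0.39), and Ccl28 (−2.07 ± 0.35) changed most, followed by Smcp (4.01-fold lower, 23.7 ± 1.42 against 5.87 ± 2.23 CPM) and Cldn9 (3.99-fold lower). Acy3 (−1.04 ± 0.17), an aminoacylase, and Amacr (−0.99 ± 0.14), a racemase of bile acid synthesis, also fell. Mgst1 (1.24 ± 0.24), Aldh1a7 (0.76 ± 0.18), Insig1 (0.99 ± 0.19), Gpam (0.85 ± 0.18) and Sesn2 (0.73 ± 0.18) rose. Proximal tubule markers fell in 2 of 13 cases, Slc7a13 (−1.21 ± 0.20) and Kap (−0.52 ± 0.12), both named after their values were seen, 4 adjusted over the list alone, with camera adjusted p = 0.00131 and adjusted p = 0.227 with an estimated correlation. Havcr1 (7.07 ± 2.11 against 2.49 ± 0.263 CPM, adjusted p = 0.0982), Cdkn1a (1.22 ± 0.38), Cyp2b10 (−0.69 ± 0.64) and Cyp2e1 (0.16 ± 0.18) did not pass, and of 16 kidney injury genes none was called, 4 higher adjusted over the list alone, with adjusted p = 0.512 with an estimated correlation. Adipose markers had a median of 1.75 with 0 of 6 called in edgeR, and Ucp1, typical of brown fat, was at 111 CPM in dose library 3. In total 545 genes were called, 252 higher and 293 lower, and 860 by DESeq2, 1359 with pooled vehicles, 890 with covariates and 352 with a replicate block. Leaving out vehicle library 1 or 2, which leaves 1, gave 113 and 62, and dose libraries 1 and 2 gave 217 and 841.

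**Figure D3:**
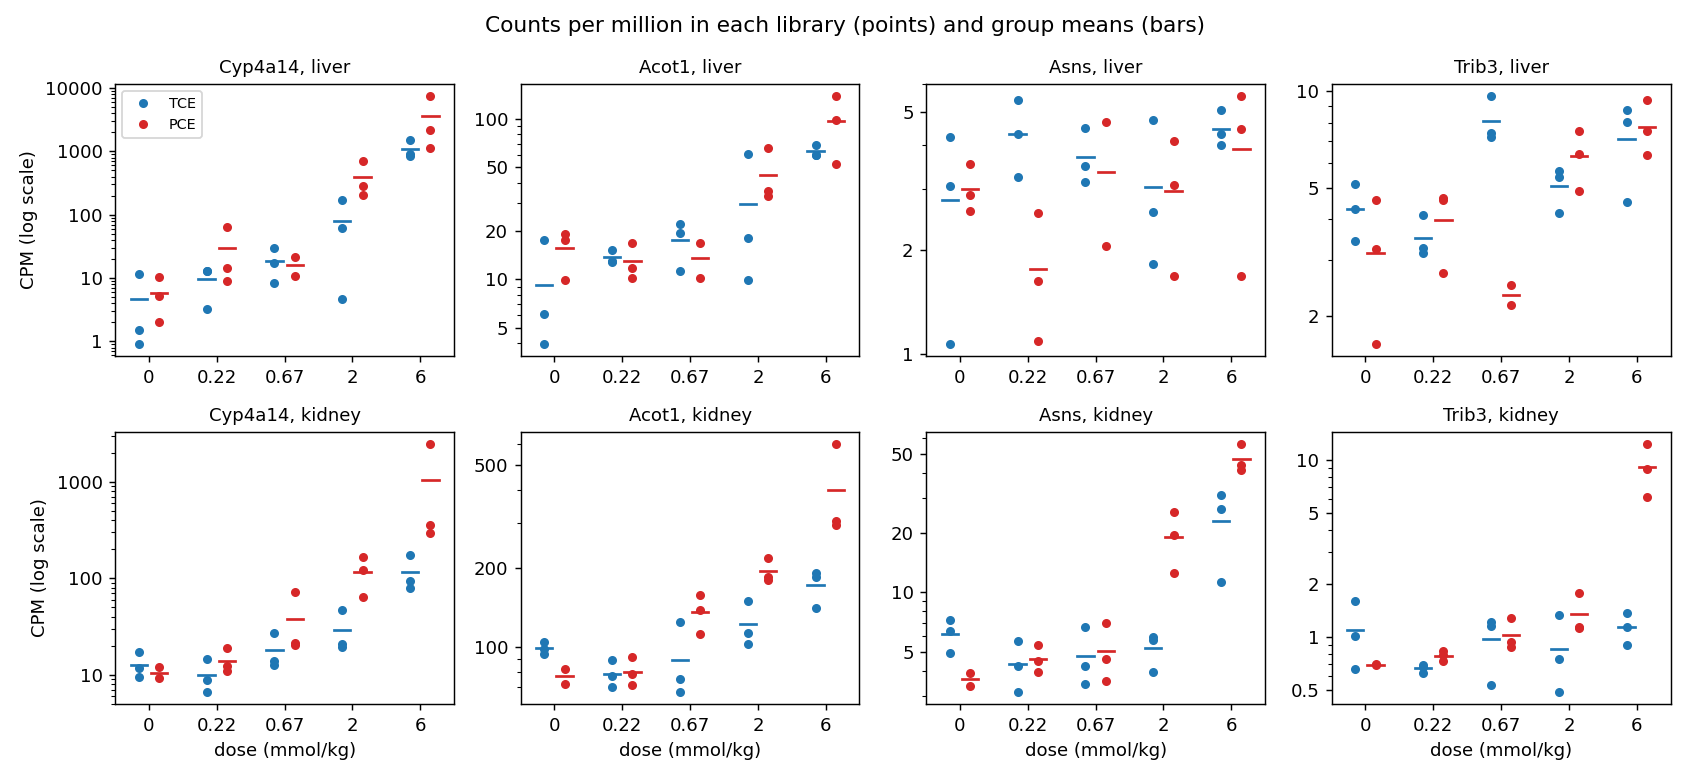
CPM of Cyp4a14, Acot1, Asns and Trib3 on a log scale (y axis) in each liver (upper row) and kidney (lower row) library by dose (x axis, mmol/kg), with points for libraries and bars for group means. Cyp4a14 means at 6 mmol/kg are 1080 CPM with TCE and 3610 CPM with PCE in liver, and 116 and 1050 CPM in kidney, and kidney Trib3 reaches 9.14 CPM with PCE.

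At 2 mmol/kg PCE the kidney calls were Asns (2.39 ± 0.40, adjusted p = 0.049) and Actb (−0.41 ± 0.07, adjusted p = 0.049), with 49 by DESeq2. Of the PPARa list 14 of 45 members rose adjusted over the list alone, none over all genes, with a median of 0.29 and adjusted p = 0.0149 with an estimated correlation. Without any 1 of 23 of the 29 libraries the count was 0, and it was 10, 16 and 4 without PCE 2 mmol/kg library 1 and 6 mmol/kg libraries 1 and 2. At 0.22 and 0.67 mmol/kg PCE edgeR called 0, with 882 and 1173 genes at an unadjusted p under 0.05 and 0 and 3 called by DESeq2. At 0.22 mmol/kg, 5 of 7 macrophage and 5 of 9 fibroblast markers were higher adjusted over the lists alone, with adjusted p = 0.043 with an estimated correlation for each, and none was called over all genes.

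At 0.22 to 2 mmol/kg in kidney none of the genes reported whatever their result was called, with adjusted p of at least 0.17. Cyp4a14 was at −0.35 to 1.20 with TCE and 0.41 to 3.47 with PCE, Acot1 at −0.33 to 0.31 and 0.06 to 1.34, Cyp2b10 at −0.81 to 0.81, Cyp2e1 at −0.06 to 0.11, Cdkn1a at 0.13 to 0.72 and Havcr1 at −0.74 to 1.12.

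Across doses in kidney, Cyp4a14 rose by 0.82 per rank with TCE (adjusted p = 0.0463) and by 1.74 with PCE (adjusted p = 0.00234), Acot1 by 0.63 with PCE, and Havcr1 by 0.32 with PCE (adjusted p = 0.041). The calls of Cyp4a14 with TCE and of Havcr1 were lost in 14 of 24 and 14 of 23 alternatives, and without PCE 6 mmol/kg library 2 Havcr1 was at 0.27 (adjusted p = 0.136). Acot1 (0.22) and Havcr1 (0.08) with TCE, and with TCE and PCE Cyp2b10 (−0.34 and −0.34), Cyp2e1 (−0.01 and 0.03) and Cdkn1a (−0.04 and 0.22), did not pass. The TCE trend called 7 genes, Acaa2, Acot2, Cyp4a14, Gsto1 and Phgdh higher and Kmo and Erich6b lower, of which all but Cyp4a14 were named after their values were seen. The PCE trend called 467, 268 higher and 199 lower, and DESeq2 called 136 and 953. The PPARa list rose with both, by 2 of 43 members for TCE and 32 of 44 for PCE, 20 and 37 adjusted over the list alone, with adjusted p = 0.0326 and 0.0198 with an estimated correlation. The TCE count was 0 without any 1 of 10 libraries, namely vehicle 1 and 3, each of 0.22 mmol/kg, 0.67 mmol/kg 1 and 2 and each of 6 mmol/kg, 12 without 0.67 mmol/kg library 3 and 31 without 2 mmol/kg library 2. The PCE count was 298 without vehicle library 2 and 226, 299 and 191 without 6 mmol/kg libraries 1, 2 and 3. It was 191 also without the 4 libraries with the most adrenal or brown fat RNA.

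The kidney responses to both chemicals at 6 mmol/kg differed for 3 genes, each higher with PCE. Chac1 differed by 3.93 ± 0.68 (adjusted p = 0.0381), Trib3 by 3.66 ± 0.53 (adjusted p = 0.00556) and Acot2 by 1.40 ± 0.24 (adjusted p = 0.0365). Cyp4a14 differed by 3.44 (95% interval 1.15 to 5.72, adjusted p = 0.397), Acot1 by 1.57 (0.82 to 2.32), Havcr1 by 1.28 (−0.06 to 2.62) and Fgf21, chosen after its values were seen, by 5.18 (2.80 to 7.57), Cyp2b10 by 0.96, Cyp2e1 by 0.17 and Cdkn1a by 1.73, none past the adjusted threshold. The PPARa list was higher with PCE, with 1 of 45 members called, 24 adjusted over the list alone, a median difference of 0.43 and adjusted p = 0.0141 with an estimated correlation. The gluconeogenesis and fasting list had 0 of 14 called, 3 adjusted over the list alone, a median of 0.60 and adjusted p = 0.0469 with an estimated correlation. DESeq2 called 49 genes. The count was 0 without TCE vehicle library 3 or PCE vehicle library 1 or 2, 5 without TCE 2 mmol/kg library 1, 39 without PCE 6 mmol/kg library 2, and 1 without any 1 of 14 others.

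Fold changes of both chemicals in kidney had Pearson's r = 0.203 and Spearman's rho = 0.264 across 14216 genes, with 4 genes such as Asns raised by both against 0.16 for independent lists, and 9 lowered against 0.33. At 0.22, 0.67 and 2 mmol/kg the responses differed for 0 genes in edgeR, with 637, 2279 and 598 at an unadjusted p under 0.05 and 0, 85 and 2 by DESeq2. Cyp4a14, Acot1, Cyp2b10, Cyp2e1, Cdkn1a and Havcr1 differed by −0.16 to 2.28 there, with adjusted p of at least 0.206. Set directly against TCE without the vehicles, PCE gave 500 genes at 0.67, 10 at 2 and 126 at 6 mmol/kg. Differences present in vehicle enter these counts too. The count at 0.22 mmol/kg was 1 without TCE 2 mmol/kg library 2 or 3, at 0.67 mmol/kg 3 and 1 without TCE 0.67 mmol/kg libraries 1 and 2, and at 2 mmol/kg 1 without PCE 2 mmol/kg library 1. The kidney vehicle groups differed for 0 genes in edgeR, with 1158 at an unadjusted p under 0.05 and 0 by DESeq2, and Cyp4a14, Acot1, Cyp2b10, Cyp2e1, Cdkn1a and Havcr1 lay between −0.87 and 0.05.

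The liver and kidney responses at 6 mmol/kg were set against each other. With TCE the liver response minus the kidney response was above 0 for Cyp4a10 (4.43 ± 0.87, adjusted p = 0.00725), Cyp4a31 (2.87 ± 0.51) and Ehhadh (2.57 ± 0.41, adjusted p = 0.000717), and below 0 for Clic3 (−3.68 ± 0.54), Slc13a5 (−3.13 ± 0.69) and Slc13a2os (−2.36 ± 0.56), an antisense gene whose reads cannot be separated from its partner's without the strand setting, which was not given. The PPARa list had 6 of 46 members higher in liver, 18 higher and 1 lower adjusted over the list alone, a median of 0.67 and adjusted p = 0.0336 with an estimated correlation. With PCE the difference was above 0 for Rad51b (4.14 ± 0.72), Rnf180 (4.02 ± 0.79) and the defensin gene Defb1 (3.05 ± 0.40), and below 0 for Gstp3 (−3.96 ± 0.51) and Spink6 (−4.58 ± 1.04). Cyp4a14 (4.67 ± 1.30, adjusted p = 0.104 with TCE, and 2.65 ± 1.32 with PCE) and Acot1 (1.97 ± 0.58 and 0.26 ± 0.61) did not pass, nor did Cyp2b10 (1.62 and 1.10), Cyp2e1 (0.17 and 0.41), Cyp7a1 (0.51 and −3.15), Cdkn1a (1.15 and 0.36) and Havcr1 (−2.40 and −0.96). The PPARa list was mixed with PCE, with 3 of 46 members called higher and 2 lower, 11 and 5 adjusted over the list alone, and adjusted p = 0.95 with an estimated correlation. Both tissues shared 59 genes raised by PCE, against 5.63 for independent lists, and 45 lowered, against 9.05, with 6 in opposite directions. With TCE 0 genes called by edgeR were shared, where independent lists give 0.0435 raised and 0.0975 lowered.

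In all 49 genes differed between tissues for TCE, 30 higher in liver and 19 lower, and 106 for PCE, 56 and 50, with 191 and 329 by DESeq2. For TCE the count was 126, 137 and 14 without liver vehicle libraries 1, 2 and 3, 29, 32 and 25 without liver dose libraries 1, 2 and 3, 19 and 23 without kidney vehicle libraries 1 and 2, and 23 and 17 without kidney dose libraries 1 and 2. For PCE it was 52 and 238 without liver dose libraries 1 and 2, 40 and 26 without kidney vehicle libraries 1 and 2, and 59 without kidney dose library 1. A replicate block of same-numbered liver and kidney libraries gave 44 for TCE. For PCE it gave 61, 49 of them shared with the 106.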

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

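The tests of explanations and of other splits in this part were written after the results were seen, while the differences between responses were planned. Responses that differed between the chemicals or between the tissues, by a test of the difference itself, are given first.

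In kidney at 6 mmol/kg, the response to PCE exceeded that to TCE for 3 genes, Chac1 (3.93), Trib3 (3.66) and Acot2 (1.40). Trib3 lost its call in 3 of 38 alternatives, Acot2 in 18 and Chac1 in 25. The PPARa list had a median difference of 0.43 and the list of gluconeogenesis and fasting 0.60. In liver at 0.67 mmol/kg, 3 genes differed, Orm2 (8.80), Slc13a5 (5.70) and Herpud1 (−2.40), and the acute phase list had a median difference of 2.61. The TCE vehicle libraries with high acute phase RNA enter this difference, and without vehicles, PCE set directly against TCE gave 4.17 for Orm2, 1.76 for Slc13a5, −1.46 for Herpud1 and an acute phase median of 1.00, with 0 genes called by edgeR and 819 at an unadjusted p under 0.05. In the alternatives run, Orm2 lost its call in 12 of 35 and Slc13a5 and Herpud1 in 11 each. The TCE response differed between liver and kidney for 49 genes, among them Cyp4a10 (4.43), Cyp4a31 (2.87), Ehhadh (2.57), Clic3 (−3.68), Slc13a5 (−3.13) and Slc13a2os (−2.36), and by a median of 0.67 for the PPARa list. Slc13a5 lost its call in 11 of 16 alternatives, Slc13a2os in 9, Cyp4a10 in 1 and the other 3 in 0. The PCE response differed for 106 genes, among them Rad51b (4.14), Rnf180 (4.02), Defb1 (3.05), Spink6 (−4.58) and Gstp3 (−3.96). Spink6 lost its call in 7 of 14 alternatives, Rad51b in 1 of 14 and the other 3 in 0 of 15.

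Genes called lower at 6 mmol/kg PCE in liver were GC-rich, with a median GC content 11.1 points above that of genes called higher. With every library thinned to 1 total, 682 genes were called, 405 of them lower. The vehicle and 6 mmol/kg liver libraries were both deep by design, so thinning could hardly decide on depth as a cause here. Comparisons of the lower liver doses with vehicle, where depth differed, were not run on thinned counts. With slopes as covariates the median of the 469 genes went from −0.77 (MAD 0.33) to −0.43 (MAD 0.35) while the median SE went from 0.19 to 0.21, 460 stayed below 0 and 50 stayed called, so calls ended with smaller folds and a GC content bias between the libraries may account for part of the pattern. A response to PCE also stays open, since 45 genes were lower in both liver and kidney against 9.05 for independent lists, though these 45 had a median GC content of 54.1%, above the 49.8% of all tested genes. The slopes differ with the dose group, so that a covariate can also take out part of a response.

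Acute phase genes lower at 6 mmol/kg TCE in liver were weighed against the vehicle libraries. Against the PCE vehicle group the list's median was 0.02 with a MAD of 0.48, where it was −1.23 against the TCE vehicle group, which argues against a response to TCE as the cause. High acute phase RNA in vehicle libraries is a candidate explanation, since 0 of 23 members were called lower by edgeR against the PCE vehicle group, and Saa1 was at 19600 and 11300 CPM in 2 of the 3 TCE vehicle libraries. What raised these genes in those libraries was not tested.

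Clock genes changed at 6 mmol/kg TCE in liver were tested against length or GC bias between the libraries. With the slopes as covariates 3 of the 5 stayed called, Dbp (3.39), Npas2 (−2.26) and Nr1d2 (2.30), which argues against that bias as the whole cause for these 3. Cry1 (−1.23 ± 0.31, adjusted p = 0.0778, from −1.19) and Nfil3 (−0.75 ± 0.24, adjusted p = 0.192, from −0.85) lost the call at similar fold changes. All 5 moved the same way in kidney, with 0 called there by edgeR, where Dbp was at 2.75 ± 0.63 (adjusted p = 0.0821). In liver at 6 mmol/kg PCE, Nr1d2 (1.85) and Npas2 (−1.08, adjusted p = 0.0341) were called in the same directions. Dbp, Cry1 and Nfil3 were not called there, and Npas2 is named there after its values were seen. Another time of day at sampling and a response to TCE cannot be told apart, since the sources used here give no time for each animal. Dbp and Npas2 lost their calls in 0 of 38 alternatives, pooled vehicle groups among them. The clock genes were not set against the PCE vehicle group alone, so a part played by the uneven TCE vehicle libraries also stays open.

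Comparisons of 3 against 3 libraries make 10 splits, too few for a share under 0.05. Real counts and the highest counts of other splits in liver were 0 and 0 at 0.22 mmol/kg TCE, 1 and 4403 at 0.67, 1 and 1633 at 2, and 172 and 4 at 6 mmol/kg. For liver PCE they were 1 and 3980 at 0.22, 24 and 2 at 2, and 770 and 13 at 6 mmol/kg, and for the vehicle groups 0 and 1092. In kidney with TCE they were 0 and 0, 1 and 1, 0 and 220, and 25 and 1 from the lowest to the highest dose. Of 100 splits for each trend, under 5 gave as many calls, a share under 0.05 that is not adjusted over the trends. For PCE the counts were 1566 against at most 886 in liver (1 split, the real one) and 467 against 75 in kidney (1). By that share chance can be excluded at that level for PCE, but such splits cannot exclude a structure of the libraries that follows dose. In liver the GC slopes differed between vehicle and 6 mmol/kg PCE, and with covariates 266 genes were called, 44 of them shared. In kidney 716 were called with covariates, 443 of them shared. For TCE in kidney the real count was 7 against 4 (1), but 0 with a replicate block and 0 without any 1 of 10 libraries. For TCE in liver 2 splits gave as many as the real 105, and the other gave 2299. A structure of the samples other than dose thus gave the larger count. With covariates the real count for TCE in liver was 0, so no conclusion on chance is drawn for TCE. For the differences between responses in liver at 0.22, 2 and 6 mmol/kg the real counts were 0 by edgeR (631, 914 and 1169 genes at an unadjusted p under 0.05, and 4, 3 and 43 calls by DESeq2) against at most 4831, 3024 and 1134. With a real count of 0 all 100 splits give as many whatever the data, so these splits say nothing about chance. For the TCE response between tissues chance cannot be excluded, with 49 calls against at most 61 (2 of 30 splits). Other splits of liver libraries with far more calls than the real one point to a structure of the samples that does not follow dose.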

How the results depend on the processing

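Covariates, fits without sets of libraries and tests per transcript were added after seeing the data. Over settings other than leaving out 1 library, named genes kept their status 2033 times, lost the call 196 times and gained it 31 times. With 1 library left out these were 7120, 446 and 12 times. Lists did so 3711, 555 and 69 times over the other settings, and 9 changed direction. A kept status means called in the same direction, or uncalled in both fits. Direction was not compared for genes and lists uncalled in both fits. Counts stayed within 1.5 times 144 times and moved 104 times, and with 1 library left out 613 and 222 times. The cause of a moved value was not tested unless given.

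Doses are given in mmol/kg. RLE gave 2 at liver TCE 2. Without a filter, counts were 0 at liver TCE 0.67, 5 and 461 at liver PCE 2 and 6, 11 at kidney TCE 6, 0 at kidney PCE 2 and 1 for the kidney TCE trend. Libraries were not treated as paired, since the labels do not say what a number marks and not every correlation at the same number passed 0.1. It did in 8 of 26 to 10 of 30 pairs between doses and in 15 of 28 liver and kidney pairs, where the median was 0.105 against −0.048 at other numbers, so that pairing of tissues stays open. The titles number the libraries in the same order of groups in both tissues, without saying whether equal numbers mark the same animal. The main comparison of tissues treated the libraries as independent. A replicate block gave 0 and 103 at liver TCE 0.67 and 6, 0, 0 and 3 at liver PCE 0.22, 0.67 and 2, 0 for the liver difference at 0.67, 68 for the liver TCE trend, 0 and 14 at kidney TCE 0.67 and 6, 0 and 352 at kidney PCE 2 and 6, and 0 for the kidney TCE trend.

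DESeq2 gave 29, 42, 57 and 350 for liver TCE and 29, 51, 187 and 1532 for liver PCE from low to high dose, 4, 53, 3 and 43 for the liver differences, 137 for the liver vehicles, and 438 and 2383 for the liver trends of TCE and PCE. In kidney it gave 0, 33, 0 and 166 for TCE, 0, 3, 49 and 860 for PCE, 0, 85, 2 and 49 for the differences and 136 and 953 for the trends. Between tissues it gave 191 and 329.

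Pooled vehicles gave 2 and 103 at liver TCE 0.67 and 6, 36, 7, 268 and 1613 for liver PCE, 35 and 43 at kidney TCE 0.67 and 6, and 49 and 1359 at kidney PCE 2 and 6. The chemical's own libraries alone, fewer than in the shared fit, gave 0, 0 and 43 at liver TCE 0.67, 2 and 6, 0, 0 and 0 at liver PCE 0.22, 0.67 and 2, 0 and 11 at kidney TCE 0.67 and 6, and 0 at kidney PCE 2. Linear dose gave 55 for liver TCE, 49 for kidney TCE and 1498 for kidney PCE. PCE set directly against TCE gave 77, 0, 65 and 67 in liver, and 500, 10 and 126 in kidney at 0.67, 2 and 6, counts that differences present in vehicle also enter. Thinned libraries gave 143 and 682 at liver TCE and PCE 6, within 1.5 times.

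Covariates gave 0, 0 and 54 at liver TCE 0.67, 2 and 6, 0, 2, 1 and 318 for liver PCE, 7 and 3 for the liver differences at 0.67 and 6, 14 for the liver vehicles, 0 and 266 for the liver trends, 0 and 60 at kidney TCE 0.67 and 6, 890 at kidney PCE 6, 7 for the kidney difference at 6, and 1 and 716 for the kidney trends. Without 12 liver libraries of low length slope, liver TCE 6 gave 1151, where the vehicle libraries kept had higher length slopes than the dose libraries. For liver PCE 6 that fit leaves 1 vehicle library, assumed to vary like the other groups. Without kidney TCE 0.67 library 3 and TCE 2 library 2, kidney TCE 0.67 and 6 gave 0 and 49, kidney PCE 2 gave 0 and the TCE trend 62. Without also TCE 6 library 2 and PCE 6 library 3, fewer than in the shared fit, these gave 0, 0, 0 and 8 (1 gene shared), kidney PCE 6 gave 652 with 448 shared, and the PCE trend 191. A replicate block of same-numbered liver and kidney libraries gave 44 for the TCE response between tissues, and 61 for that of PCE with 49 shared.

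With 1 library left out, where kidney PCE vehicle and liver PCE 0.67 keep 1 library assumed to vary like the other groups, liver TCE ranged 0 to 75, 0 to 62, 0 to 39 and 28 to 224 from low to high dose, liver PCE 0 to 38, 0 to 8, 0 to 55 and 56 to 1258, the liver differences 0 to 15, 0 to 65, 0 to 3 and 0 to 35, the liver vehicles 0 to 97, and the liver trends 18 to 258 and 457 to 2510. In kidney TCE ranged 0 to 200, 0 to 1 and 0 to 55 at 0.67, 2 and 6, PCE 0 to 16 and 62 to 841 at 2 and 6, the differences 0 to 1, 0 to 3, 0 to 1 and 0 to 39, and the trends 0 to 31 and 191 to 515. Between tissues, where a library of the 4 groups compared was left out, counts ranged 14 to 137 and 26 to 238.

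Lists that changed direction with pooled vehicles were acute phase at liver PCE 0.22, 2 and 6 (adjusted p = 9.95e-05, 0.0354 and 0.802) and at kidney PCE 0.22 and 0.67 (0.946 and 0.845), hepatocyte at kidney PCE 0.22 (0.0158), and cell cycle at kidney TCE 0.67 (0.616) and kidney PCE 2 (0.779). Lipogenesis at liver PCE 6 did so with covariates (0.0136). Lists uncalled in both fits were not checked for direction.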

Other observations

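The test of synthetase genes in this part and the genes named were chosen after values were seen. In kidney at 6 mmol/kg PCE, further genes rose beside Asns, Trib3 and Chac1, while the planned list of ER stress and amino acid response had 4 members higher and 6 lower, with camera adjusted p = 0.259 in the lower direction. The transcription factor gene Atf5 rose by 3.33 ± 0.60 (adjusted p = 0.00324), Mthfd2 by 2.54 ± 0.33 (adjusted p = 0.000132), Eif4ebp1, a repressor of translation, by 1.90 ± 0.22 (adjusted p = 3.51e-05) and Pck2, the mitochondrial PEP carboxykinase, by 0.83 ± 0.10. The efflux transporter gene Abcb1a rose by 1.56 ± 0.31 (adjusted p = 0.00501). In liver the same dose gave −0.22 ± 0.52 for Atf5, −0.41 ± 0.37 for Mthfd2 and −0.10 ± 0.16 for Eif4ebp1, none called, and the responses of Atf5 (−3.55), Mthfd2 (−2.97) and Eif4ebp1 (−2.01) differed between the tissues.

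A hypothesis for Asns, Trib3 and Chac1 is that they rise in a response to amino acid limitation, in which genes of cytosolic aminoacyl-tRNA synthetases also rise. Of 20 synthetase genes tested, 6 were called higher and 0 lower by edgeR, against 246 of 14196 other genes called higher (Fisher's exact p = 9.2e-07, across genes, which are not independent). Without Gars, Iars and Sars, which were seen before the list was written, 3 of 17 were called higher (Fisher's exact p = 0.00301). The 6 were Sars (1.19), Gars (0.74), Iars (0.62), Lars (0.51), Aars (0.43) and Yars (0.30). The 17 genes had a median change of 0.19. The other genes were not matched for level or SE, so both Fisher tests may also reflect how easily small changes are called. The response to amino acid limitation stays a hypothesis that may fit these 3 genes, and no amino acid was measured here. The synthetase test did not set it against other stress responses, so it cannot tell them apart.

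In liver, Scand1 was at 13.5 to 45 CPM in the TCE libraries, at 25.9, 1.08 and 2.63 CPM in PCE vehicle libraries 1, 2 and 3, and at 0.217 to 1.72 CPM in the libraries dosed with PCE. Fdx2 was at 2.45 to 3.97 CPM in the TCE libraries, at 3.31, 0.176 and 1.31 CPM in the PCE vehicle libraries and at 0.0184 to 0.828 CPM in the libraries dosed with PCE.

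Some kidney libraries held RNA of genes typical of other tissues. Cyp11b1, an adrenal enzyme gene, was at 566 CPM in TCE 0.67 mmol/kg library 3. Ucp1, typical of brown fat, was at 111 CPM in PCE 6 mmol/kg library 3, 107 CPM in TCE 6 mmol/kg library 2 and 90.4 CPM in TCE 2 mmol/kg library 2. Alb was at 83 CPM in TCE vehicle library 2.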
